A study of Medicago sativa with 9 samples.

How the data were processed

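Leaves of alfalfa (Medicago sativa), a forage legume whose genome carries 4 copies of each of 8 chromosomes, were sampled 0, 12 and 48 h into treatment with selenite, the Se(IV) form of selenium, at 100 mg per kg, with 3 libraries at each time. Poly(A) RNA was fragmented and sequenced as paired ends with an insert of 300 ± 50 bp, per the labels' protocols. The submitters' processing notes name HISAT and StringTie, without version or role. The genome build, the annotation and the handling of reads that match several chromosome copies are not given in the sources used here. No untreated libraries at 12 or 48 h are among the samples, so that treatment and time of sampling cannot be separated, and the labels do not say whether the 3 libraries of a time came from separate plants. The p-values therefore measure the spread between these libraries, which may be technical.

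The deposited table lists 164632 genes with their position, a description, GO and KEGG terms, and 2 values per library. The first is a whole-number read count per gene, not normalized, as deposited by the authors. The second is an FPKM value computed by the authors, which is listed as 1e-04 wherever the count is 0, and was read here as 0. In all, 63624 genes had no count in any library. Gene names are the descriptions in the deposited table, and coordinates are those of the table.

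Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 50878. Counts were scaled by trimmed mean of M values (TMM) and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with 1 mean per time and all 9 libraries in the fit, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The standard error (SE) of a log2 change is its size divided by the square root of F. The design written before the data were examined assumed FPKM alone and named limma on log2(FPKM + 1). Because the table also holds counts, the count test became the main one and limma 3.58.1 an alternative. Median-of-ratios factors, planned on FPKM, were likewise computed on counts. The common biological coefficient of variation was 0.843. Counts were also summed over genes that share a description and a numbered chromosome, which gave 24684 groups, called summed copies below, with a coefficient of variation of 0.685. Near-identical copies can exchange reads, so the value of a single copy is uncertain where the summed copies differ from it.

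A set of 34 gene lists was written as patterns on the descriptions before the data were examined. Each was tested against all other genes with camera at a preset correlation of 0.01, and again with the correlation estimated from the libraries. Some patterns took in members by accident, such as YUCCA10 in the clock list, and the list of organelle-encoded genes held only nuclear genes. Tests without these members were added after the data were seen. The grouping of clock genes by part of the day was written after values had been seen, and a pattern for LUX that had matched the ion channel POLLUX was corrected after the first run. Enrichment of GO and KEGG terms of 10 to 500 members used tested genes that carry such a term as background and a one-sided Fisher's exact test. Terms are named only where genes and summed copies both passed. List totals are sums of FPKM, compared by two-sided exact permutation over the 6 libraries, where the smallest possible p is 0.1. Named genes follow a rule fixed beforehand. Its first part takes, per comparison, the 5 higher and 5 lower called genes of largest change with a mean FPKM of at least 10 in the higher group, separate ranges and an informative description. Its second part takes, for each list with a called member at 12 or 48 h against 0 h, the called member of smallest adjusted p. For a gene with no count in a whole group, the change is given as a bound against a floor of 3 counts per library. With such genes at their bound the median of chaperones at 48 h against 0 h was -0.32 in place of -0.33, and the medians of the other lists that passed did not change.

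The smallest library held 39936347 counts and the largest 56137145, and 3 counts correspond to 0.0534 to 0.0751 CPM. Intervals and floors of this kind cover counting error only. The test was run on simulated counts in which 200 of the 50878 genes were changed. For 12 h against 0 h it recovered 0% of 4-fold, 20% of 16-fold and 42.9% of 64-fold changes with 1 false call, and for 48 h against 0 h 0%, 13.2% and 35% with 0 false calls.

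To compare how libraries draw on chromosome copies, 2407 groups with 1 member on each of the 4 copies and at least 200 counts in every library were used. For each pair of libraries, the share of reads that would have to move to other copies to make the pair equal was computed per group, and its median taken. Alternative tests written beforehand changed the pseudocount, the filter, the scaling, the libraries in the fit, the variance trend, library weights, a replicate block and single libraries. Added after the data were seen were DESeq2 1.42.0, limma on log2(FPKM + 1), summed copies, library totals alone, omission of alike libraries, and libraries of like copy usage summed to 1. Figures were drawn with matplotlib 3.10.9.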

Results

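Gene expression was measured by poly(A) RNA sequencing in alfalfa leaves at 0, 12 and 48 h of selenite treatment, with 3 libraries per time. Tested genes held 97.9% to 98.5% of the counts of each library. The 10 most abundant genes held 6.95% to 12.2% of the counts of a library. TMM factors lay between 1.20 and 1.27 at 12 h, against 0.856 to 0.988 at 0 h and 0.836 to 0.933 at 48 h. Scaling by library totals alone would move the median log2 change of all genes to 0.39 at 12 h against 0 h, to -0.14 at 48 h against 0 h and to -0.54 at 48 h against 12 h.

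Libraries of one time were not equally separate in their use of chromosome copies. The 3 libraries of 12 h differed from each other by 8.90% to 9.05% of reads on other copies, and 48 h replicates 1 and 3 differed by 9.81%. The 3 libraries of 0 h differed from each other by 20.8% to 23.3%, and libraries of different times by 19.9% to 23.7%. The 48 h replicate 2 differed from replicates 1 and 3 by 23.6% and 22.9%. All pairs differed by more than counting noise, which does not tell separate plants from repeat libraries of 1 plant. All 9 libraries were kept. When the 3 libraries of 12 h were summed to 1, and 48 h replicates 1 and 3 to 1, a step chosen after the data were seen, edgeR called 0 genes in every comparison at an adjusted p of 0.05. It found 3776, 3870 and 4458 genes at an unadjusted p under 0.05 for 12 h against 0 h, 48 h against 0 h and 48 h against 12 h. In that fit the lone 12 h column is assumed to vary like the other groups, and no other tool was run on it. Every count of called genes given here therefore rests on treating these libraries as separate samples.

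**Figure D1:**
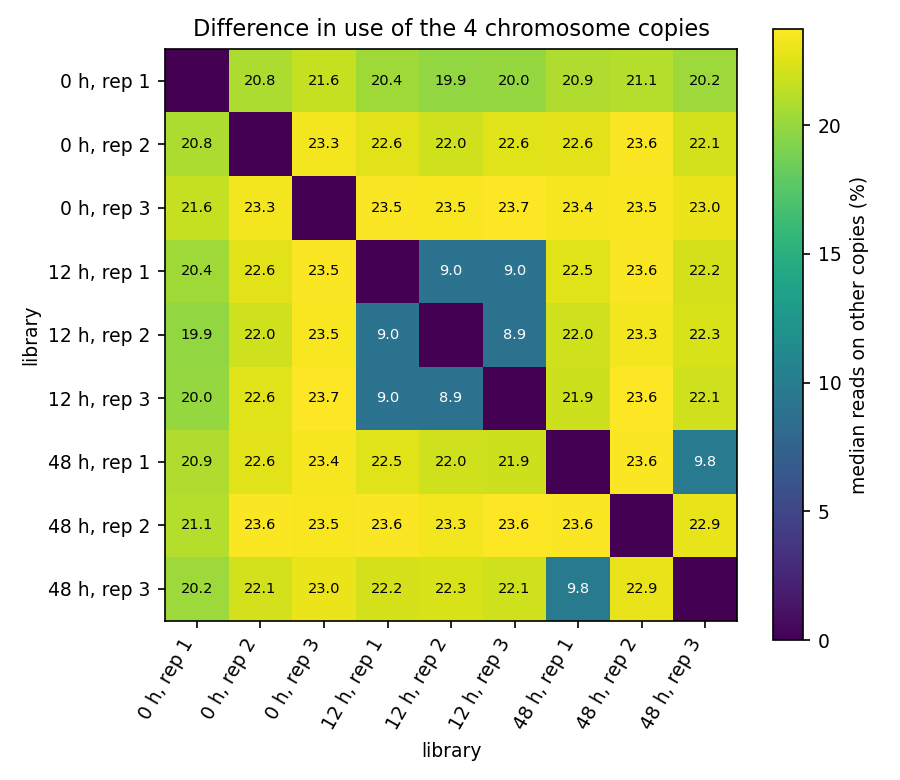
Each cell gives, for a pair of libraries, the median percent of reads that lie on other chromosome copies over 2407 gene groups; rows and columns are the 9 libraries. The 12 h libraries (8.90% to 9.05%) and 48 h replicates 1 and 3 (9.81%) stand apart from all other pairs (19.9% to 23.7%).

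The comparison of 12 h with 0 h addresses the early leaf transcriptome under selenite. Sulfate transporters fell at 12 h. Of 22 measured members 13 fell and none rose, 18 when adjusted over the list alone, and the median log2 change was -3.42. The members form only 6 summed groups, and all 6 fell (camera adjusted p = 3.46e-12 over summed copies). Their summed level went from 493.8 ± 122.5 FPKM at 0 h to 57.7 ± 8.48 at 12 h (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The camera adjusted p was 3.47e-20, and adjusted p = 0.033 with an estimated correlation. Probable sulfate transporter 3.3 (MS.gene059517, chromosome 4.4, 27616574 to 27623249) fell from 79.0 ± 17.5 to 6.50 ± 1.53 FPKM, a log2 change of -4.00 ± 0.30 (SE) with an edgeR adjusted p of 0.00142, and its summed copies fell by 4.50. A gene for 5'-adenylylsulfate reductase 3, an enzyme of sulfate reduction (MS.gene002964, chromosome 2.4, 63825599 to 63828026), fell from 429 ± 207 to 14.6 ± 9.40 FPKM, with a log2 change of -5.24 ± 0.61. The list of sulfate reduction and cysteine synthesis had 7 of 85 members lower and none higher, 7 also over the list alone, and did not pass (camera adjusted p = 0.0852).

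Genes of light harvesting and pigment synthesis fell as well. In the photosystem list 51 of 194 members fell and none rose, 85 over the list alone, with a median log2 change of -1.04 (camera adjusted p = 1.82e-17, adjusted p = 0.32 with an estimated correlation). A putative chlorophyll A-B binding protein (MS.gene34392, chromosome 1.2) fell from 276 ± 161 to 0.738 ± 0.191 FPKM, and its 5 copies all moved down. The early light-induced protein MS.gene070961, which stood at 86.1 ± 76.8 FPKM at 0 h, had no count at 12 h and was at least 744-fold lower, and all 13 copies of its group fell. Its 0 h counts were 2401, 56 and 3202, so that the bound rests on replicates 1 and 3. In the chlorophyll synthesis list 22 of 74 members fell and 1 rose (27 and 2 over the list alone, median -0.90, camera adjusted p = 1.79e-08, adjusted p = 0.32 with an estimated correlation). A putative magnesium chelatase, which inserts magnesium on the path to chlorophyll (MS.gene040934), fell by 4.58 ± 0.31 on the log2 scale. In the list of carbon fixation 8 of 142 fell and none rose (13 over the list alone, median -0.36, camera adjusted p = 0.0428, adjusted p = 0.73 with an estimated correlation), and that call was lost in 17 of 28 alternative settings, summed copies among them (adjusted p = 0.11).

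Components of the circadian clock moved in both directions. Of 87 members 9 rose and 18 fell (13 and 29 over the list alone, median -0.80, camera adjusted p = 0.000618, adjusted p = 0.32 with an estimated correlation). LHY, a clock transcription factor (MS.gene22755, chromosome 7.3, 320924 to 331166), fell from 49.5 ± 2.69 to 0.278 ± 0.0233 FPKM, a log2 change of -7.83 ± 0.25 with an adjusted p of 4.56e-05, and all 4 copies fell. Some other clock genes were singled out after values had been seen. Summed copies of EARLY FLOWERING 4 rose by 5.62 ± 0.39, those of APRR1 on chromosome 8 by 4.33 ± 0.56, while those of REVEILLE 8 changed by -5.57 ± 0.27 and those of GIGANTEA by -3.06 ± 0.27. The GO term circadian rhythm was enriched among genes called higher (20 of 216, 5.85-fold, adjusted p = 8.83e-07), and the KEGG map of the plant circadian rhythm among those called lower (40 of 272, 3.08-fold, adjusted p = 6.80e-09).

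**Figure D2:**
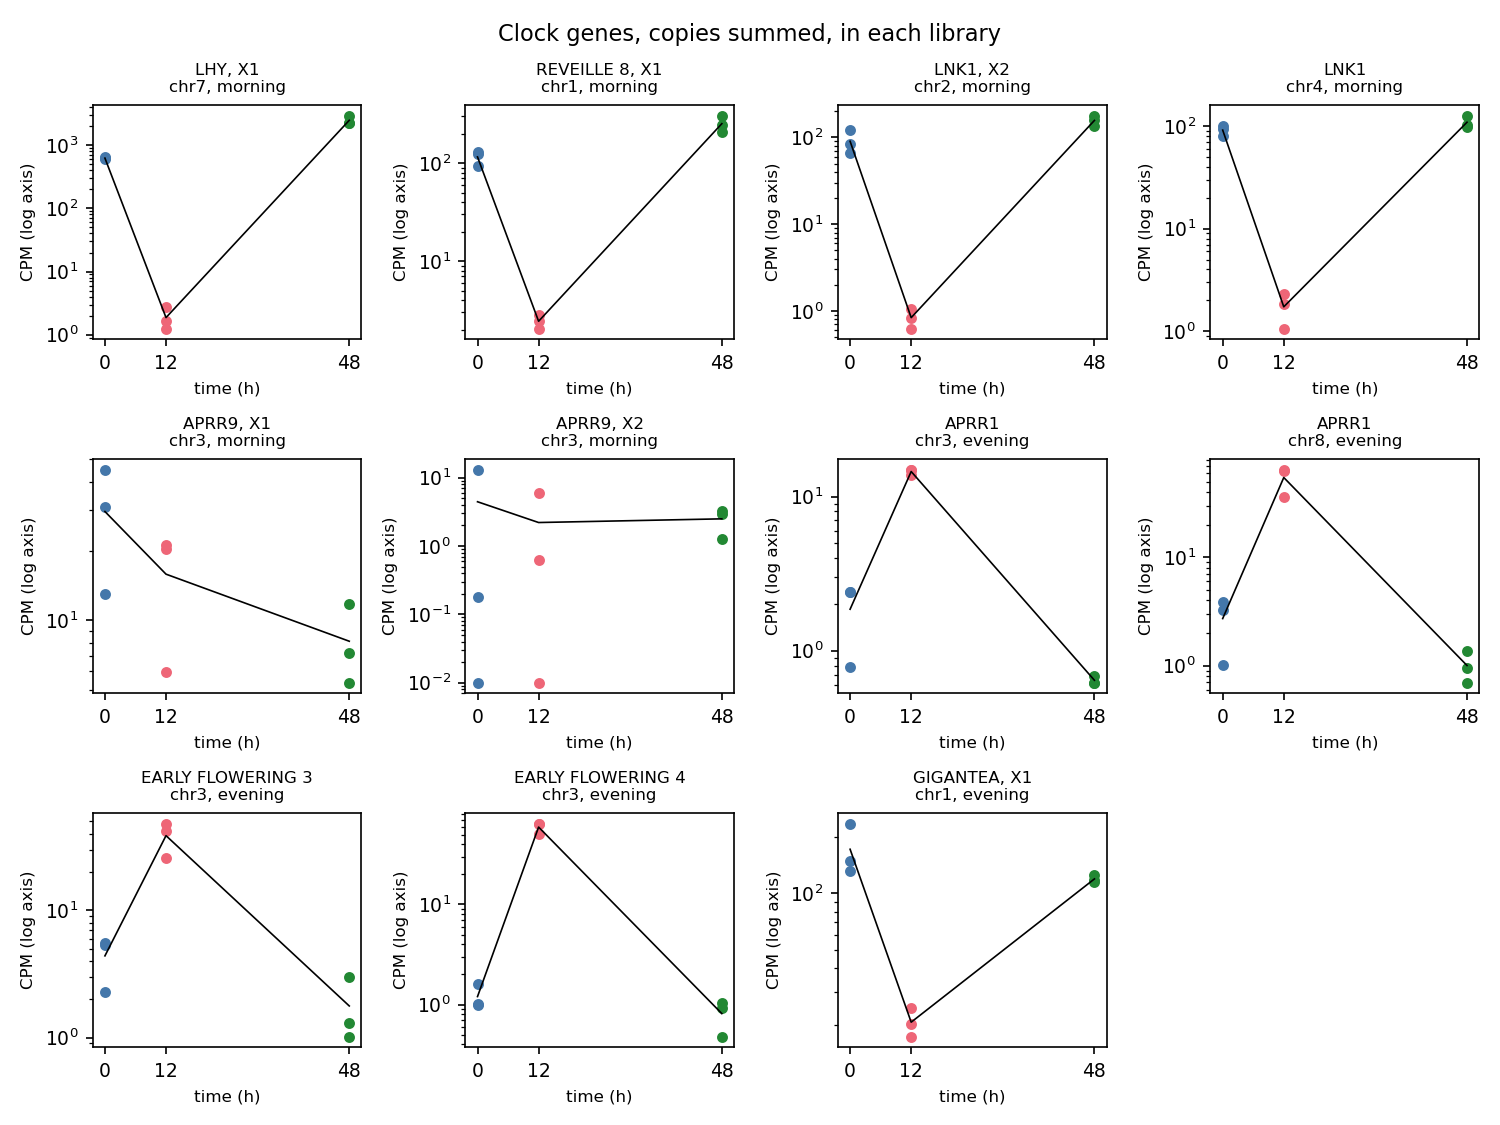
Scaled counts (CPM), on a log axis, of 11 clock genes with copies summed, against time in h; points are libraries, lines join means, and libraries without a count are drawn at the lower end. Panel titles give the chromosome and the part of the day in which the gene was placed after values had been seen; LHY, REVEILLE 8 and both LNK1 groups were low at 12 h (summed log2 changes -8.38, -5.57, -6.75 and -5.72).

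Phenylpropanoid and flavonoid genes also fell at 12 h. In the phenylpropanoid and lignin list 29 of 212 fell and 3 rose (46 and 7 over the list alone, median -0.73, camera adjusted p = 0.00048, adjusted p = 0.50 with an estimated correlation), and in the flavonoid list 20 of 256 fell and none rose (21 over the list alone, median -0.88, camera adjusted p = 3.15e-05, adjusted p = 0.32 with an estimated correlation). Phenylalanine ammonia-lyase, the entry enzyme of the pathway (MS.gene029816), fell from 81.9 ± 8.98 to 19.7 ± 2.96 FPKM. A chalcone synthase, the entry enzyme of flavonoid synthesis (MS.gene52324), fell by 4.71 ± 0.54 on the log2 scale. Aquaporins fell, with 12 of 74 lower and 1 higher (19 and 2 over the list alone, median -1.09, camera adjusted p = 5.75e-05, adjusted p = 0.11 with an estimated correlation), but their summed copies did not pass (adjusted p = 0.0659). Starch and sucrose genes (18 lower, 3 higher of 137, and 26 and 7 over the list alone, median -0.45, camera adjusted p = 0.0158, adjusted p = 0.32 with an estimated correlation) and markers of secondary wall and xylem (7 lower, 1 higher of 77, and 12 and 2 over the list alone, median -1.02, camera adjusted p = 0.0118, adjusted p = 0.82 with an estimated correlation) also passed. The last list did not pass with summed copies (median -0.28, adjusted p = 0.247). Its median turned to 0.62 where an FPKM of 5 was required. Its summed level went the other way, from 347.7 ± 145.3 to 491.4 ± 101.1 FPKM (exact permutation p = 0.3). That is a log2 ratio of 0.50 without TMM scaling, where library totals alone put the median of all genes at 0.39. The median of 1 library of 12 h lay inside the range of 0 h for the secondary wall list (-0.51, replicate 3), the phenylpropanoid list (-0.14, replicate 3) and the list of carbon fixation (-0.13, replicate 2).

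Among genes called higher at 12 h, ethylene response factor 8 (MS.gene037965) rose from 0.272 ± 0.0395 to 34.1 ± 2.99 FPKM, a log2 change of 6.47 ± 0.51. CONSTANS-LIKE 9 (MS.gene70471) and the demethylase JMJ30 (MS.gene003928) had no count at 0 h and were at least 324-fold and 233-fold higher at 12 h, and their summed copies rose by 7.77 ± 1.26 and 9.09 ± 1.32. In other genes only a single copy was called. A 26S proteasome subunit 10B copy (MS.gene064694) was at least 779-fold lower, while its summed copies changed by -0.25 ± 0.18 (adjusted p = 0.45). An S-adenosylmethionine synthase copy (MS.gene28651) was 5.87 ± 0.95 higher, with summed copies at 0.19 ± 0.31 (adjusted p = 0.76). Of 43 named entries, 33 had summed copies past the threshold. For 3 of the 43 no other copy was summed, so the summed value is no separate check. Of these, MS.gene040934 and MS.gene21118 lie outside the numbered chromosomes, where copies were not matched by description. MS.gene064694 was entered under both parts of the rule.

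In all, 2991 genes were called at 12 h against 0 h, 806 higher and 2185 lower, and 2587 summed groups, 881 higher and 1706 lower. The count was 867, 916 and 1922 without 12 h replicates 1, 2 and 3, 1991 without 48 h replicate 1, and 0 with libraries of like copy usage summed. Scaling by library totals alone turned the split to 1638 higher and 1563 lower of 3201.

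The comparison of 48 h with 0 h addresses the later leaf transcriptome under selenite. Cytosolic ribosomal protein genes fell at 48 h. Of 681 members 23 fell and none rose, 69 and 1 over the list alone, and the median log2 change was -1.16 (camera adjusted p = 7.00e-22, adjusted p = 0.32 with an estimated correlation). The members form 204 summed groups, of which 19 fell and none rose. Their summed level went from 30130 ± 2268 FPKM at 0 h to 13350 ± 5461 at 48 h, and had been 33320 ± 2026 at 12 h. The 3 libraries of 48 h had list medians of -1.48, -0.46 and -1.63 against the 0 h mean, so that replicate 2, which differs in copy usage, moved least. The plastid ribosomal proteins had none of 131 members called and a median of -0.03.

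WRKY transcription factors and genes of the phosphate transport list rose at 48 h. Of 138 WRKY members 8 rose and none fell, 23 and 1 when adjusted over the list alone (median 0.98, camera adjusted p = 2.04e-09, adjusted p = 0.43 with an estimated correlation). The members form 48 summed groups, of which 8 rose and none fell. WRKY53 (MS.gene95287, chromosome 8.1, 74027694 to 74030927) rose from 3.63 ± 0.888 to 35.4 ± 5.08 FPKM, a log2 change of 3.36 ± 0.40. In the phosphate transport list, included because selenite is carried by phosphate transporters, 4 of 31 members rose and none fell, 13 and 1 when adjusted over the list alone (median 1.91, camera adjusted p = 1.20e-07, adjusted p = 0.32 with an estimated correlation). The member named by the rule, a putative glycerol-3-phosphate transporter 1 (MS.gene34834), carries another substrate and rose by 2.71 ± 0.38. The pattern does not part such members from carriers of phosphate itself, and their number was not counted. At 12 h against 0 h the list had 2 members lower and 0 higher. The one named there, inorganic phosphate transporter 2-1 (MS.gene067922), fell by 2.47 ± 0.35. The summed list level was 236 ± 31.7 FPKM at 0 h and 830 ± 282 at 48 h. Of the 48 h libraries replicate 2 moved least in both lists, with a median of 0.77 for WRKY genes against 1.60 in replicate 3, and of 1.40 for phosphate transporters against 2.11 and 2.42 in replicates 1 and 3.

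Further named genes were called higher at 48 h, none of them from the list of defence proteins. SAR DEFICIENT 1, a regulator of systemic acquired resistance (MS.gene050758), had no count at 0 h and stood at 11.6 ± 6.34 FPKM at 48 h, at least 311-fold higher. It already had counts of 366, 294 and 275 at 12 h. This gene lies outside the numbered chromosomes, so no summed copies check its value. The carboxylesterase SAG101 (MS.gene54703) rose by 4.09 ± 0.47, the transporter ABCG36 (MS.gene011058) by 3.72 ± 0.39, a heat shock 70 kDa protein 18 (MS.gene36002) by 3.44 ± 0.47 and a putative phenylalanine ammonia-lyase (MS.gene007526) by 2.63 ± 0.29 on the log2 scale, each with summed copies past the threshold. The GO term response to chitin was enriched among genes called higher (21 of 205, 15.7-fold, adjusted p = 1.40e-15), as were defense response to fungus (18 of 420, 6.56-fold) and ethylene-activated signaling (15 of 331, 6.93-fold). The ethylene list had 13 of 217 higher and 2 lower (36 and 11 over the list alone, median 0.23, camera adjusted p = 0.0122, adjusted p = 0.32 with an estimated correlation). The list of defence proteins passed with a median of 0.59 (camera adjusted p = 0.022, adjusted p = 0.75 with an estimated correlation), although none of its 253 members was called higher and 1, the PR-1-like gene MS.gene012422, was called lower, the same as over the list alone. Its 48 h libraries had medians of 0.89, -0.14 and 1.02 and totals of 7465, 2903 and 11940 FPKM, against 4333 to 5102 FPKM at 0 h. Only replicates 1 and 3, which are alike in copy usage, were higher. The median of 48 h replicate 1 for the ethylene list (0.13) also lay inside the range of 0 h. Neither of these lists passed with summed copies (adjusted p = 0.13 and 0.43).

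Other lists that passed at 48 h were aquaporins (3 of 74 lower and 1 higher, 17 and 2 over the list alone, median -0.83, camera adjusted p = 0.000178, adjusted p = 0.20 with an estimated correlation), jasmonate genes (3 of 128 lower and 2 higher, 9 and 3 over the list alone, -0.77, camera adjusted p = 0.000178, adjusted p = 0.75 with an estimated correlation), antioxidant enzymes (-0.40, with none of 107 called by either adjustment, camera adjusted p = 0.0116, adjusted p = 0.43 with an estimated correlation), starch and sucrose genes (3 of 137 lower and none higher, 21 and 5 over the list alone, -0.39, camera adjusted p = 0.00634, adjusted p = 0.32 with an estimated correlation), chaperones (3 of 421 lower and 5 higher, 13 and 6 over the list alone, -0.33, camera adjusted p = 0.0172, adjusted p = 0.75 with an estimated correlation) and photosystem genes (1 of 194 higher and 1 lower, also over the list alone, 0.38, camera adjusted p = 0.00169, adjusted p = 0.75 with an estimated correlation). With summed copies aquaporins (median 0.02, adjusted p = 0.287) and antioxidant enzymes (median -0.24, adjusted p = 0.13) did not pass. Jasmonate genes had medians of -1.02, -1.58 and -0.37 in the 48 h libraries, and the total of replicate 3 (5365 FPKM) lay inside the range of 0 h (4505 to 7948 FPKM). Inside the range of 0 h also lay the median of chaperones in 48 h replicate 2 (-0.05) and that of photosystem genes in replicate 3 (0.27). Sulfate transporters had a median of 0.07 and no called member, and their summed level was 388 ± 45.4 FPKM. LHY stood at 248 ± 9.26 FPKM, 2.39 ± 0.19 above 0 h on the log2 scale. Single copies again moved apart from their summed groups. A lipoxygenase 6 copy (MS.gene023390) was at least 1274-fold lower, with summed copies at -0.23 ± 0.18 (adjusted p = 0.55), and a copy of protein SPA (MS.gene27061) was at least 749-fold lower, with summed copies at -0.04 ± 0.36 (adjusted p = 0.97). Of 35 named entries, 20 had summed copies past the threshold. Here no other copy was summed for 2 of the 35. Of these, MS.gene050758 lies outside the numbered chromosomes, where copies were not matched by description. MS.gene023390, MS.gene99375 and MS.gene066455 were entered under both parts of the rule.

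In all, 582 genes were called at 48 h against 0 h, 329 higher and 253 lower, and 926 summed groups, 492 higher and 434 lower. These calls depend on the 12 h libraries being in the fit. With only the 6 libraries of 0 h and 48 h in the fit edgeR called 0 genes, with 6305 at an unadjusted p under 0.05. It also called 0 with libraries of like copy usage summed, while DESeq2 on all 9 libraries called 5579. The split turned to 257 higher and 293 lower with library totals alone, 1069 and 2054 with library weights, and 1072 and 1661 without 48 h replicate 2. The count was 4, 12 and 268 without 12 h replicates 1, 2 and 3, and 493, 299 and 226 without 0 h replicates 1, 2 and 3. It was 50 and 82 without 48 h replicates 1 and 3, but 2733 without replicate 2. Each of these fits left out 1 library, so the number of libraries alone does not set the count. How far the spread of the 12 h libraries does was not tested separately.

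**Figure D3:**
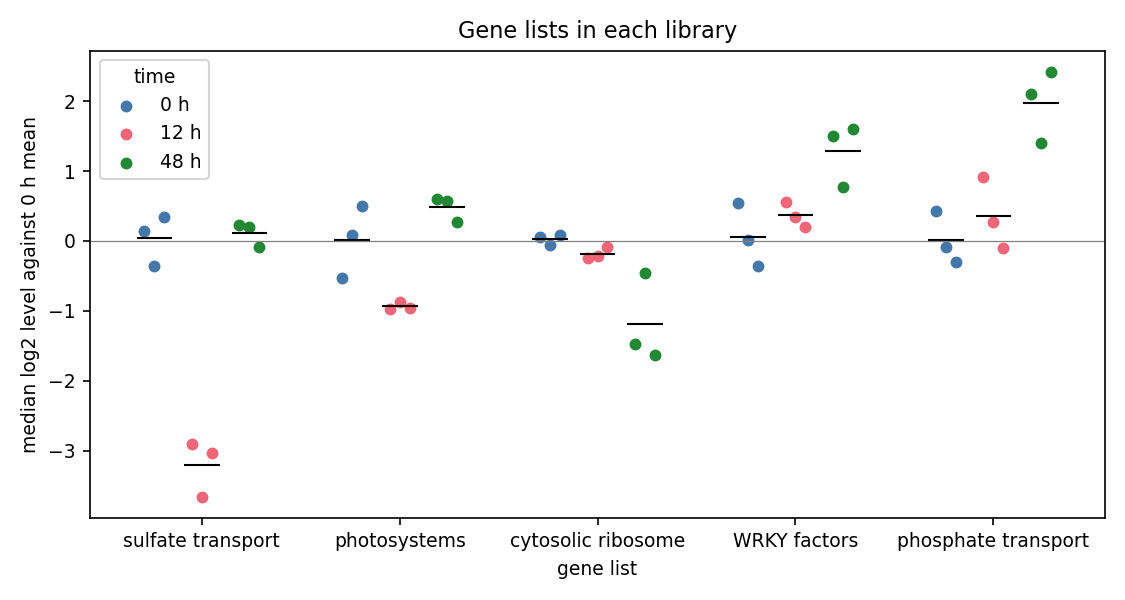
Median log2 level of 5 gene lists in each library against the mean of 0 h; points are libraries, colours times and bars group means. Sulfate transport lies between -3.66 and -2.91 at 12 h, and the cytosolic ribosome at -1.48, -0.46 and -1.63 at 48 h.

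The comparison of 48 h with 12 h addresses the change between the treated times. Sulfate transporters were higher at 48 h, with 16 of 22 members called higher and none lower (21 over the list alone, median 2.93, camera adjusted p = 2.73e-18, adjusted p = 0.043 with an estimated correlation). Photosystem genes rose, with 85 of 194 higher and 3 lower (106 and 4 over the list alone, median 1.23, camera adjusted p = 2.28e-23, adjusted p = 0.43 with an estimated correlation), and so did chlorophyll synthesis, with 22 of 74 higher and 1 lower (24 and 1 over the list alone, median 0.63, camera adjusted p = 1.50e-06, adjusted p = 0.43 with an estimated correlation). Flavonoid genes (43 higher, 2 lower of 256, and 55 and 3 over the list alone, median 1.20, camera adjusted p = 2.58e-06), phenylpropanoid and lignin genes (48 higher, 5 lower of 212, and 59 and 5 over the list alone, median 0.75, camera adjusted p = 4.52e-05) and the phosphate transport list (8 higher, none lower of 31, and 11 and 2 over the list alone, median 1.62, camera adjusted p = 0.000355) also passed, each at adjusted p = 0.43 with an estimated correlation. WRKY genes had 20 of 138 higher and none lower (26 over the list alone, median 0.88, camera adjusted p = 0.000355, adjusted p = 0.57 with an estimated correlation). Auxin genes had 31 of 292 higher and 15 lower (42 and 22 over the list alone, median 0.75, camera adjusted p = 0.0130, adjusted p = 0.45 with an estimated correlation). Defence proteins had 34 of 253 higher and 5 lower (44 and 5 over the list alone, median 1.02, camera adjusted p = 0.00257, adjusted p = 0.56 with an estimated correlation) and clock genes had 20 of 87 higher and 12 lower (24 and 17 over the list alone, median 0.12, camera adjusted p = 0.0373, adjusted p = 0.53 with an estimated correlation). The clock call was lost in 15 of 28 alternative settings, with medians from -0.33 to 0.38. Auxin genes and defence proteins did not pass with summed copies (adjusted p = 0.0575 and 0.186). In 48 h replicate 2 the median of defence proteins (-0.14) lay inside the range of 12 h (-0.26 to -0.02). Cytosolic ribosomal proteins had 67 of 681 lower and 9 higher (74 and 10 over the list alone, median -0.86, camera adjusted p = 1.70e-08, adjusted p = 0.53 with an estimated correlation). A strictosidine synthase family gene (MS.gene014029) had no count at 12 h and was at least 950-fold higher at 48 h, and its summed copies rose by 7.97 ± 0.86. CONSTANS-LIKE 12 (MS.gene56038) had no count at 48 h and was at least 457-fold lower by its 12 h mean, with summed copies at -8.68 ± 1.91. Its 12 h counts were 416, 430 and 4405, so that the bound rests mainly on replicate 3 and would be lower from replicates 1 and 2 alone. The KEGG map of ribosome biogenesis was enriched among genes called lower (32 of 296, adjusted p = 3.98e-06).

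In all, 5378 genes were called at 48 h against 12 h, 3543 higher and 1835 lower, and 4252 summed groups. The count was 1883, 1756 and 2711 without 12 h replicates 1, 2 and 3, 2454 and 2843 without 48 h replicates 1 and 3, and 0 with libraries of like copy usage summed. Scaling by library totals alone turned the split to 2390 higher and 4264 lower.

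Most genes called at 12 h against 0 h were not called at 48 h against 0 h. A missing call does not show that a change had ended, since the 48 h test recovered only 13.2% of 16-fold changes in simulated counts. Of the 2991 genes called at 12 h, 2052 had the opposite change called between 12 h and 48 h, 1682 lower and then higher and 370 higher and then lower. Both comparisons use the 12 h libraries with opposite sign, which by itself favours such reversals, and no expected number for unchanged genes was computed. A change in the same direction was called at both times for 140 genes, 98 higher and 42 lower, where independent lists of those sizes would share 5.21 and 10.9. Both comparisons use the 0 h libraries, which by itself raises the shared number. In 20 simulations all 9 libraries were drawn anew from the 0 h means, unchanged between times, with 1 dispersion per gene for all times. The shared number was 0 there, but the test calls hardly any gene in such data, so that this sets no scale for the 140. Across genes, which are not independent replicates, the covariance of the log2 changes was 1.02 against 0.65 in these simulations, a difference of 0.374, and the correlation 0.313 against 0.503. The measured 0 h libraries were less alike (r of 0.62 to 0.67) than those of 12 h (0.77 to 0.82). A dispersion common to all times may therefore put the simulated covariance too low, and the difference is not read as shared change.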

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

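DESeq2, limma on log2(FPKM + 1), summed copies, library totals alone, omission of alike libraries, lists without accidental members and libraries of like copy usage summed were chosen after seeing the data. For the counts below the cause of a change was not tested unless fewer libraries or another set of genes entered the fit. Counts of called genes are given in the order 12 h against 0 h, 48 h against 0 h and 48 h against 12 h, where the main counts were 2991, 582 and 5378. They were 5849, 1507 and 10640 with limma on log2(FPKM + 0.1), 9420, 1971 and 13578 on log2(FPKM + 5), 8256, 2037 and 12845 on log2(FPKM + 1), 8042, 1957 and 12592 on TPM. They were 6478, 2225 and 10139 after quantile normalization, 6084, 3123 and 20243 with library weights, 9088, 5579 and 12403 with DESeq2, and 1852, 158 and 3332 without a filter. Some settings without TMM also moved the median of all genes at 12 h. It was 0.39 with library totals alone, but 0.01 with median-of-ratios factors. With limma it was 0.45, 0.31 and 0.14 on log2(FPKM + 0.1), log2(FPKM + 1) and log2(FPKM + 5), so that it also moved with the pseudocount. The share of calls that were higher at 12 h was 26.9% in the main test, 67.1% on TPM, 48.3% after quantile normalization and 51.2% with library totals alone. For 48 h against 0 h the count was 315 without a variance trend, 926 with summed copies and 0 with only those 6 libraries in the fit. Leaving out 12 h replicate 2 and 48 h replicate 3 together gave 278, 0 and 353 genes, and summing libraries of like copy usage gave 0, 0 and 0, also with copies summed, from fewer columns. At an unadjusted p under 0.05 the latter edgeR fits held 3776, 3870 and 4458 genes, or 2426, 2518 and 2830 summed groups. Without single libraries the counts ranged from 867 to 4440, from 4 to 2733 and from 1756 to 7336. A replicate block gave 817, 0 and 1771 genes, with 6726 at an unadjusted p under 0.05 for 48 h against 0 h. The numbers do not pair the samples, since deviations of same-numbered libraries correlated between -0.0294 and 0.0214. The shared changes of 12 h and 48 h numbered 140, and 601 after quantile normalization.

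The numbers of gene lists past the threshold, 10, 11 and 11, were 1, 0 and 1 with an estimated correlation. For 48 h against 0 h the number was 7 without a filter, 7 with summed copies and 6 with copies and libraries of like copy usage summed. Without single libraries the numbers ranged from 9 to 13, from 8 to 13 and from 10 to 13. The sulfate transport list passed in all 28 alternatives at 12 h against 0 h, with medians from -3.68 to -1.02 and adjusted p up to 0.0332. The cytosolic ribosome list at 48 h against 0 h passed in 27 of 28, with medians from -1.68 to -0.91. The secondary wall list turned to 0.62 where an FPKM of 5 was required. For named genes, summed copies turned the direction of MS.gene62506 at 12 h (-0.52), MS.gene038116 (-0.17) and MS.gene46649 (0.60) at 48 h against 0 h and MS.gene028847 at 48 h against 12 h (-0.39). With like libraries summed as well these were -0.49, -0.12, 0.55 and -0.22. Over all alternatives, 1661 values of named genes kept direction and call and 587 lost the call. Depth limits the 342 genes called at 12 h against 0 h with no count in a whole group to a bound on their change.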

Other observations

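Values of some groups outside the lists that passed are given here. No list total could pass a test, since the smallest possible exact permutation p is 0.1 (adjusted p = 0.243 or more against 0 h). Cell wall expansion genes had a summed level of 1289 ± 436 FPKM at 0 h, 3451 ± 355 at 12 h and 1916 ± 505 at 48 h, with 16 of 254 members called higher and 8 lower at 12 h, and the list did not pass (camera adjusted p = 0.21), and the totals of 48 h overlapped those of 0 h (exact permutation p = 0.2). Abscisic acid and dehydration genes stood at 3916 ± 436, 6477 ± 469 and 7399 ± 693 FPKM, although more of the 301 members were called lower (22) than higher (9) at 12 h (camera adjusted p = 0.77). These and the preceding totals lack TMM scaling. Library totals alone put the median log2 change of all genes at 0.39 at 12 h against 0 h. Nitrite reductase, which follows nitrate reductase in nitrogen assimilation (MS.gene047831), fell from 55.8 ± 22.7 to 2.63 ± 0.573 FPKM at 12 h. The list of the methionine cycle and selenium-handling enzymes had 7 of 64 lower and 2 higher at 12 h, 18 and 5 over the list alone (median -0.75, camera adjusted p = 0.0621), and a median of -0.54 at 48 h against 0 h (camera adjusted p = 0.0834). The glutathione list had 4 of 86 lower and none higher at 12 h, and the glutathione S-transferases 3 of 181 higher and 8 lower, and none of these 3 lists passed in any comparison of the main test.

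Apart from the planned list tests, the tests on clock genes, copy usage, the proteasome comparison and 48 h replicate 2 were chosen after the result was seen. Those on gene length, depth and other splits of the libraries were chosen before. The depth test was extended afterwards to genes that were not called. At 12 h clock genes placed in the morning lay below those placed in the evening by a median summed log2 difference of -8.77, and at 48 h the difference was 1.83. With library totals alone the summed change of LHY, the clock member of smallest adjusted p at 12 h, was -7.94. TMM factors of 0.836 to 1.27 are too close to have given another outcome. They are too small to make a change of this size, but the test adds nothing beyond that. For LHY, assignment of reads to other copies is argued against by a summed change of -8.38. A candidate explanation is the time of day, since 12 h after the start may fall in the opposite part of the daily cycle and 48 h in the same part. Some genes did not follow their placement. GIGANTEA, placed in the evening, fell. The APRR9 groups, placed in the morning, were not called at 12 h (-0.90 and -1.01, edgeR adjusted p = 0.39 and 0.83). At 48 h summed LHY and REVEILLE 8 lay above 0 h by 1.99 and 1.13 (edgeR adjusted p = 0.014 and 0.034). The placement gives only morning or evening and was made after values had been seen. These exceptions therefore do not decide on the time of day. With 0 untreated libraries at 12 h, selenite and the daily cycle cannot be told apart, for the clock genes or for the photosystem and sulfate transporter genes that returned by 48 h.

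The fall of cytosolic ribosomal proteins at 48 h is not explained by gene length, since their median lay at -1.03 against genes matched on length. A shift in library composition would have moved the proteasome list alike, and the ribosomal median lay at -1.03 against it. Whether the pattern belongs to the alike libraries 48 h replicates 1 and 3 stays open. The only other library, replicate 2, had a median of -0.46 against the 0 h mean, below the 0 h libraries (-0.06 to 0.09), but it is a single library, and the demand for at least 2 libraries, which keeps this test open, was added after the value had been seen. An effect of treatment or time remains open as an untested biological explanation.

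Genes with no count in a whole group were 342 of the 2991 called at 12 h. For these genes depth is argued against by their expected counts of 13.1 or more per library (median 155.2). Calling, and the filter of FPKM 1 in 3 libraries, both favour genes of high expected count. The shares under 3 were therefore low in advance and add no support. They were 0% of those called and 0.382% of all 1048 tested genes at 0 in either group, called or not. Copy usage set by time or treatment is argued against by the 0 h libraries, which differed from each other by a median of 21.6%, close to the 22.5% between times. The 12 h libraries differed by a median of 8.997%, which is consistent with 3 libraries from 1 plant or clone, and 48 h replicates 1 and 3 may likewise share a plant; if so, n counts libraries and not plants, and differences between plants enter each comparison. Of called genes with other copies at 12 h, 22.3% had a summed change under 1 or opposite, which leaves open how many of these calls come from plants of different copy content or from reads assigned to other copies.

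For 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. All splits but the real one mix both times within each group, which raises the spread there and favours 0 calls in advance. The counts of these splits therefore add no support. With the 6 libraries concerned, the real split called 2890 genes at 12 h against 0 h, 0 at 48 h against 0 h and 7314 at 48 h against 12 h, and the highest of the other splits 0 in each, so that 1, 10 and 1 of the 10 splits called as many as the real one.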
